A study of Mus musculus with 24 samples.

How the data were processed

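RNA of microglia sorted from 24 mouse retinas was measured by sequencing, with 1 library per retina. The deposited values used here are expected counts per gene, estimated numbers of reads that need not be whole, with 1 table per retina, per the file headers. The submitters' processing notes name the mm10 build, Salmon 1.4.0, R 4.0.3 and DESeq2 1.30.1, without saying which step each served. The aligner, the annotation release and any filter are not given in the sources used here. TPM and FPKM columns deposited beside the expected counts, and 1 deposited table of FPKM values with 24 columns of per-sample values, were not used. Estimated counts depend on how reads that match several genes were shared out, which affects paralogs and pseudogenes most.

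Expected counts were rounded to whole numbers per retina and summed over the eyes of each animal, or over the eyes of 1 animal with the same grade for the stage comparisons. The animal was therefore the replicate in the comparisons of groups. DBA/2J animals 1 and 5 had eyes of different grades, so the trend had 7 sums of 5 animals and the stage fit 17 sums of 15 animals, taken as independent there. Groups, animal numbers, eyes and grades came from the labels. The files hold 47729 gene IDs, of which 47224 matched a symbol in the GRCm38 annotation, the build that mm10 also names, and coordinates are from that annotation. Among 91 pairs of retinas of the same group, the smallest chi-square per degree of freedom was 102 and at most 0.253% of values were identical, so no library was counted as a duplicate. The upper limit that a count of 0 allows is 3 counts of the library total, which covers counting error only.

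Genes were tested with edgeR 4.0.16 in R 4.3.3, by its quasi-likelihood F test with TMM scaling. The filter on low counts was filterByExpr with a minimum count of 10 and a minimum total of 15. The 3 comparisons of groups (12-month DBA/2J against Gpnmb+, 12-month against 6-month DBA/2J, and 6-month DBA/2J against Gpnmb+) shared 1 fit of 15 animals. A trend used the stage scores 0, 1 and 2 within 12-month DBA/2J, and mild, moderate and severe retinas were each set against Gpnmb+ in a fit of 17 sums. P-values were two-sided and adjusted by Benjamini and Hochberg over the genes of a comparison, with a threshold of 0.05. CPM per animal, or per animal and grade, are counts divided by the TMM-scaled total of the genes kept by the filter, within the fit they belong to, and multiplied by 1e6. CPM per retina are counts divided by the library total and multiplied by 1e6. The script was tested on simulated counts drawn from the real means, library sizes and edgeR's dispersions per gene, with genes independent of each other. In them 200 genes with a mean log2 CPM of at least 4 were changed 2-, 4- or 8-fold.

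The 27 gene lists were fixed before the data were examined, as were the tests, the first set of alternatives to them and the rule for named genes, and none of the lists was chosen on these samples. They cover microglia states, pathways, and markers of other retinal and blood cells that the sort could let through. Lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. Alternatives were camera with an estimated correlation and fry, which asks whether a list's genes move one way without comparing them with other genes. Of 562 list entries, 560 were in the files, the others being Lilrb4a and Lrrc33.

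Named were Gpnmb and Tyrp1, a fixed set of 13 genes (Apoe, Spp1, Lgals3, Clec7a, Itgax, Trem2, Axl, P2ry12, Tmem119, Cx3cr1, Csf1r, Sall1 and Fcrls), up to 12 called genes per direction with an average log2 CPM of at least 4, and up to 4 members with the smallest p of each list discussed. No gene met the part of the rule on called genes. The homeostatic list and the lists called by fry alone were added to the lists discussed after their values were seen. Fcgr1, Ccl12, the mitochondrial genes and the X- and Y-linked genes, as well as genes named beside counts of calls, were chosen after their values were seen. The values of 1 other gene are not reported here.

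Alternatives for genes set before the data were examined were DESeq2 1.42.0, RLE scaling, no filter on low counts, a filter of at least 50 counts in 5 sums, each retina as a replicate, retinas with a random animal effect (limma's voomLmFit), the compared groups alone, leaving out 2 retinas under 20% of the median total (2270610 counts), the animal number as a block, and leaving out each animal. Chosen after seeing the data were leaving out the 5 retinas with fewer than 10000 genes, which removes 2 Gpnmb+ animals, sample quality weights, only the retina with the larger total of each animal, the animal number as a block in the stage comparisons, and an exact permutation test of summed CPM per list. For lists, RLE scaling and leaving out low-depth retinas or 1 animal at a time were also chosen then. Figures and tables were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. The 5 retinas stayed in the reported values.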

Results

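Microglia, the resident macrophages of nervous tissue, were sorted from single mouse retinas as CD11b+ and FCRLS+ cells without Ly6c, and their RNA was sequenced per retina. DBA/2J is an inbred strain that develops an age-related glaucoma and lacks functional Gpnmb and Tyrp1. The control strain, DBA/2J Gpnmb+, carries a working Gpnmb on the same background. The 24 retinas came from 15 animals in 3 groups of 5. At 12 months there were 10 retinas of DBA/2J mice and 9 of Gpnmb+ mice. At 6 months there was 1 retina from each of 5 DBA/2J mice, labelled as early disease. The labels grade each 12-month DBA/2J retina as mild (3 retinas of 2 animals), moderate (4 retinas of 3 animals) or severe (3 retinas of 2 animals). Counts of the eyes of an animal were summed, so that n is the number of animals. For the grades, eyes were summed by animal and grade, and DBA/2J animals 1 and 5, whose eyes differ in grade, enter with 2 sums each.

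Depth differed between retinas. The total count per retina was 1706775 to 20081114 in 12-month DBA/2J, 12043911 to 17993059 in 6-month DBA/2J and 977886 to 14845311 in Gpnmb+. Genes with at least 1 count numbered 10703 to 15046, 13818 to 16716 and 3469 to 14468 in the same order. Fewer than 10000 genes were found in 5 retinas, which belong to Gpnmb+ animals 1, 2 and 3. Mitochondrial genes took 2.07 ± 0.65% (SD, 10 retinas) of the counts in 12-month DBA/2J, 1.15 ± 0.34% (5 retinas) in 6-month DBA/2J and 2.23 ± 1.10% (9 retinas) in Gpnmb+.

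**Figure D1:**
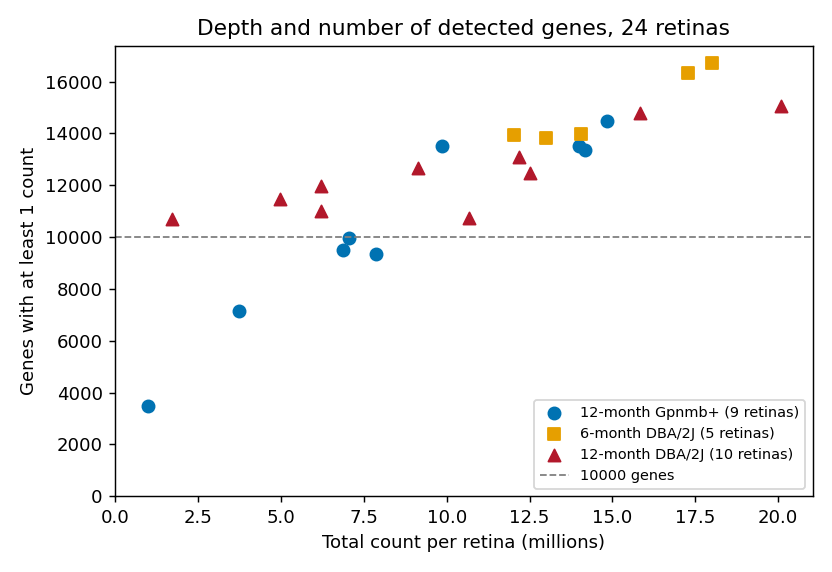
Total count (x axis) and number of genes with at least 1 count (y axis) of the 24 retinas, 1 point per retina, coloured by group. The dashed line marks 10000 genes, and the 5 retinas under it are from Gpnmb+ mice, with a lowest value of 3469 genes.

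Gpnmb, a membrane glycoprotein gene (chromosome 6, 49036546 to 49070929, GRCm38), had reads in 1 of the 9 Gpnmb+ retinas, the left eye of animal 5, with 459 counts or 30.9 CPM (counts scaled to the same library total). The other 8 Gpnmb+ retinas and the 15 DBA/2J retinas had 0 counts. A count of 0 allows up to 0.149 to 1.76 CPM per retina in 12-month DBA/2J, 0.167 to 0.249 CPM at 6 months and 0.202 to 3.07 CPM in Gpnmb+. Tyrp1, a melanosomal enzyme gene (chromosome 4, 80834123 to 80851719), had 0 counts in the 24 retinas. Counts per gene do not show which allele was read. The reads in 1 retina, from an animal whose other eye had 0 counts, thus do not check the genotype label. Counts of 0 check no label here either, since 8 control retinas were at 0 as well.

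The first comparison asked how microglia of 12-month DBA/2J retinas differ from those of the Gpnmb+ strain at the same age. Lists of neurodegenerative microglia (MGnD), complement, MHC, lipid handling, oxidative phosphorylation, ribosomal protein and monocyte genes rose in DBA/2J by camera with a preset correlation, and immediate early and heat shock genes fell. With an estimated correlation none of these calls held (smallest adjusted p = 0.289 with an estimated correlation). Apoe, which encodes the lipid carrier apolipoprotein E, had 10970 ± 7956 CPM (SD, n = 5) against 1971 ± 1765 (n = 5), a log2 fold change of 2.48 ± 0.58 (SE). C1qa, a chain of the complement starter C1q, had 4326 ± 554 CPM against 2770 ± 414, and Jun, an immediate early transcription factor, had 2238 ± 499 CPM against 5384 ± 2310 (n = 5 each). No single gene passed the adjustment over all genes.

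By edgeR's quasi-likelihood test, 0 of 12977 genes had an adjusted p under 0.05, and the smallest was 0.313. At an unadjusted p under 0.05 there were 676 genes, 358 higher and 318 lower, where evenly spread p would give 649 and other splits of the animals had a median of 458. Of 12 alternatives, DESeq2 gave 108 genes, retinas fitted with a random animal effect gave 8, and the other 10 gave 0. In simulated counts of this comparison DESeq2 made 60 false calls and edgeR 1, and edgeR recovered 50% of genes changed 8-fold, 29.9% at 4-fold and 1.49% at 2-fold. The changed genes had a mean log2 CPM of at least 4, so recovery of less abundant genes was not measured.

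Immediate early genes, which respond to stimulation within minutes, and heat shock genes were lower in DBA/2J: 22 of 23 tested had negative log2 fold changes (median -1.16), 17 were lower and 0 higher at an unadjusted p under 0.05, and 17 were lower adjusted over the list alone. The adjusted p was 6.04e-14 by camera with the preset correlation and 0.0497 by fry, and adjusted p = 0.289 with an estimated correlation. Log2 fold changes were -1.27 ± 0.32 for Jun, -3.95 ± 1.02 for Egr2, -1.87 ± 0.50 for Ier2 and -1.20 ± 0.33 for Btg2. Btg2 was lower in 5 of 5 DBA/2J animals than in any Gpnmb+ animal, against 3 of 5 for Jun, 3 for Egr2 and 4 for Ier2. For a gene fixed beforehand, 0.79% of the splits of 10 animals give a full separation in either direction. Btg2 was named for its small p, so this share does not hold for it. How many of all genes separate fully was not counted. Hspa1a and Hspa1b are near-identical, so reads can be divided between them. Without the 5 retinas under 10000 genes the median was -0.75 and the camera adjusted p 0.0043.

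The MGnD list holds genes that microglia are known to induce near damaged neurons. Of 36 tested, 29 had positive log2 fold changes (median 0.73), 11 were higher and 1 lower at an unadjusted p under 0.05, and 6 were higher adjusted over the list alone. The adjusted p was 0.00657 by camera and 0.0309 by fry, and adjusted p = 0.554 with an estimated correlation. Fry also pointed up, without passing, for rod markers (14 of 17 negative) and for Muller glia and astrocyte markers (5 of 6 negative). Since fry does not compare a list with other genes, its upward calls in this comparison need not be particular to a list. The camera call was lost with 1 retina per animal (0.101) and without Gpnmb+ animal 3 or 4 (0.0552 to 0.0685). Apoe (chromosome 7, 19696109 to 19699188) was higher in 4 of 5 DBA/2J animals than in any Gpnmb+ animal, with an edgeR adjusted p of 0.337. The next members by p encode lysosomal cathepsins, with log2 fold changes of 0.69 ± 0.17 for Ctsz, 0.49 ± 0.14 for Ctsd and 0.84 ± 0.24 for Ctsl. Among genes fixed in advance the log2 fold changes were 1.38 ± 0.51 for the receptor kinase Axl, 0.38 ± 0.18 for the lipid receptor Trem2, 1.59 ± 1.38 for Spp1, 1.69 ± 2.06 for Lgals3, 2.26 ± 1.49 for Itgax and -1.14 ± 0.50 for Clec7a.

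Complement genes had 11 of 13 positive changes (median 0.64), 5 higher and 0 lower at an unadjusted p under 0.05, and 3 higher adjusted over the list alone. The adjusted p was 0.00951 by camera and 0.0309 by fry, and adjusted p = 0.514 with an estimated correlation. The camera call was lost without the retinas under 10000 genes (0.0545), with 1 retina per animal (0.101) and without Gpnmb+ animal 4 (0.0552). C1qa (chromosome 4, 136895917 to 136898803) had a log2 fold change of 0.64 ± 0.13 and C1qb of 0.73 ± 0.16. C4b, a later complement component that can share reads with its paralog C4a, had 130 ± 59.5 CPM against 4.27 ± 5.85 (n = 5 each). These 3 genes, named for their small p, were each higher in 5 of 5 DBA/2J animals than in any Gpnmb+ animal.

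MHC genes serve antigen presentation. Of 17 tested, 5 were higher and 0 lower at an unadjusted p under 0.05 and 4 higher adjusted over the list alone (median 0.32). The adjusted p was 0.0402 by camera and 0.0374 by fry, and adjusted p = 0.554 with an estimated correlation. The camera call was lost with RLE scaling (0.0682), with 1 retina per animal (0.0765) and without 12-month DBA/2J animal 2, 3 or 4 or Gpnmb+ animal 1, 3, 4 or 5 (0.0712 to 0.359). The members that were higher belong to class I and its processing: H2-D1 (chromosome 17, 35262730 to 35267499) had 1707 ± 493 CPM against 893 ± 168 (n = 5 each), and log2 fold changes were 0.96 ± 0.22 for H2-K1, 0.76 ± 0.18 for B2m and 0.86 ± 0.26 for Psmb8. H2-D1 and H2-K1 belong to a family of close paralogs that can share reads, and DBA/2J has another MHC haplotype than the C57BL/6 reference, in all groups alike.

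Genes of lipid handling, many under the LXR receptors, had 17 of 20 positive changes (median 0.83), 4 higher and 0 lower at an unadjusted p under 0.05, and 3 higher adjusted over the list alone. The adjusted p was 0.00657 by camera and 0.0358 by fry, and adjusted p = 0.514 with an estimated correlation. The camera call was lost without the retinas under 10000 genes (0.0502) and with 1 retina per animal (0.0765). Apoe, which the MGnD list also holds, was followed by Npc2, a lysosomal cholesterol carrier (0.74 ± 0.24), Soat1, which esterifies cholesterol (0.98 ± 0.40), and Apoc2, with 3.75 ± 3.46 CPM against 0 ± 0 (n = 5 each).

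Oxidative phosphorylation genes had 33 of 36 positive changes (median 0.44) and 1 higher at an unadjusted p under 0.05, Cox4i1 (0.61 ± 0.24). Ribosomal protein genes had 34 of 36 positive (median 0.40) and 6 higher, led by Rpl8 (0.72 ± 0.24). For either list 0 members passed adjusted over the list alone. Camera gave adjusted p of 0.0174 and 0.0373 and fry 0.0735 and 0.157, and with an estimated correlation adjusted p = 0.554 and 0.88. The first call was lost with 1 retina per animal (0.0982) and without 12-month DBA/2J animal 1, 2 or 4 or Gpnmb+ animal 3, 4 or 5 (0.0522 to 0.0859). The ribosomal call was lost with RLE scaling (0.0901), with 1 retina per animal (0.497), without low-depth retinas (0.0789) and without 12-month DBA/2J animal 1, 2 or 4 or Gpnmb+ animal 3, 4 or 5 (0.108 to 0.303). Reads of ribosomal protein genes can be divided with their processed pseudogenes.

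The Ly6c gate should reduce only those monocytes and recruited macrophages that carry Ly6c. Markers of monocytes and recruited macrophages had 6 of 6 positive changes (median 1.39) and 1 higher adjusted over the list alone. That gene was Lyz2, a lysozyme gene that the MGnD list also holds, with 857 ± 409 CPM against 248 ± 168 (n = 5 each). The adjusted p was 0.0373 by camera and 0.0358 by fry, and adjusted p = 0.514 with an estimated correlation. The camera call was lost without the retinas under 10000 genes (0.776), without low-depth retinas (0.0789), with 1 retina per animal (0.225) and without 12-month DBA/2J animal 1, 2, 3, 4 or 5 or Gpnmb+ animal 1, 2, 3, 4 or 5 (0.0803 to 0.681).

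Homeostatic microglia genes, which mark resting microglia, did not pass by camera (adjusted p 0.0581, median -0.03, 33 tested, 2 higher and 1 lower at an unadjusted p under 0.05). Camera called the list lower with RLE scaling (0.0286), without the retinas under 10000 genes (0.0373), without 12-month DBA/2J animal 3 (0.0488) and without Gpnmb+ animal 1 (0.0329). Log2 fold changes were 0.75 ± 0.16 for Olfml3, whose 12-month DBA/2J animal 5 lay below the other 4, -1.71 ± 0.39 for Rhob, 0.64 ± 0.18 for Tmem119, -0.37 ± 0.18 for Tgfbr1 and -0.22 ± 0.19 for the purine receptor P2ry12. They were -0.43 ± 0.28 for the transcription factor Sall1, 0.83 ± 1.21 for Fcrls, -0.03 ± 0.19 for Cx3cr1 and 0.04 ± 0.24 for Csf1r. Lysosomal genes passed by fry alone (34 tested, 13 higher and 2 lower at an unadjusted p under 0.05, 12 and 1 adjusted over the list alone, median 0.38, adjusted p 0.0476 by fry and 0.167 by camera, and adjusted p = 0.794 with an estimated correlation), with Ctss at 0.65 ± 0.15.

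The other lists did not pass by camera in this comparison. Medians and camera adjusted p were 0.41 and 0.456 for interferon response, -0.26 and 0.0745 for inflammatory cytokines, 0.07 and 0.995 for cholesterol synthesis, -0.17 and 0.456 for glycolysis, 0.33 and 0.995 for proliferation, and -0.21 and 0.456 for TGF-beta signalling. For markers of other cells they were -0.54 and 0.884 for rods, -0.78 and 0.884 for Muller glia and astrocytes, 0.36 and 0.456 for border-associated macrophages, 0.23 and 0.995 for endothelium, and 0.83 and 0.418 for pigment cells, which passed by fry (0.0482, 3 tested, 0 past an unadjusted p of 0.05, Best1 at 2.04 ± 1.29, adjusted p = 0.554 with an estimated correlation). Camera called inflammatory cytokines lower without 12-month DBA/2J animal 2 (0.0315). It called rod markers higher without the retinas under 10000 genes (0.00194) and without Gpnmb+ animal 2 (0.0174), and that animal had a summed rod CPM of 10700 against 477 to 1760 in the other 4 Gpnmb+ animals. The lists of cones (0.995), ganglion cells (0.769), bipolar, amacrine and horizontal cells (0.472), neutrophils (0.884) and lymphocytes (0.884) had 1 or 2 tested members, and red cells had 0.

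**Figure D2:**
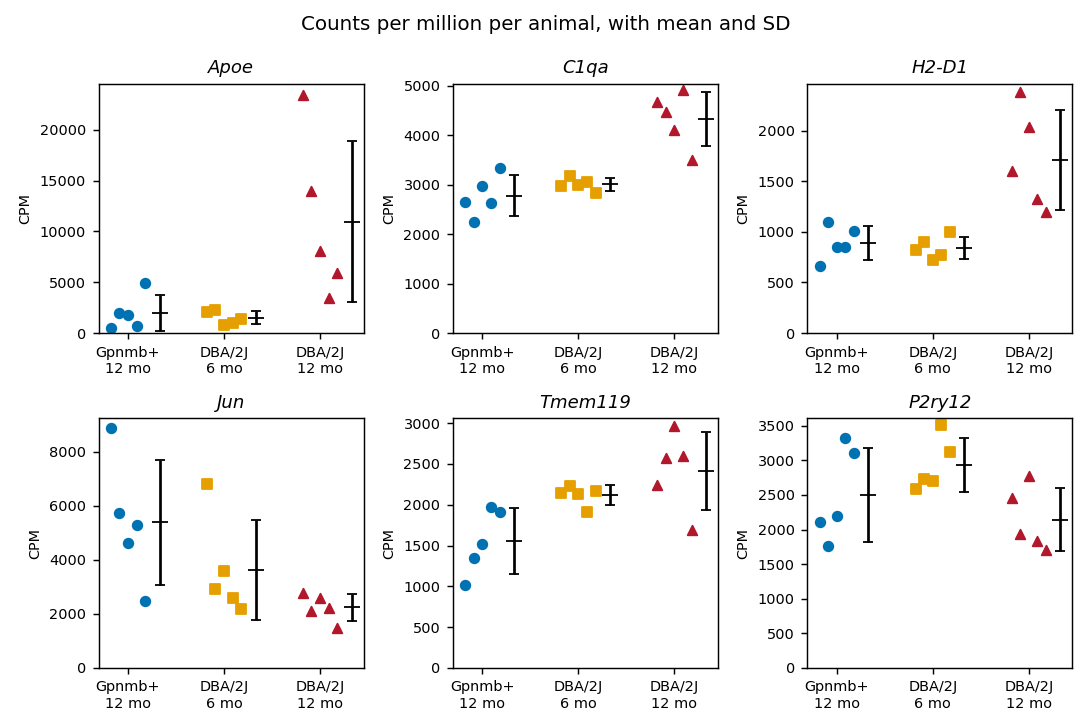
CPM (y axis) of 6 genes per animal (points, n = 5 per group) with the mean and SD, for 12-month Gpnmb+, 6-month DBA/2J and 12-month DBA/2J. The 5 points of 12-month DBA/2J lie above the other animals for C1qa (lowest 3490 CPM) and H2-D1 (lowest 1200 CPM), and 4 of 5 lie above the highest Gpnmb+ animal for Apoe (4900 CPM).

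The second comparison asked what differed between 12 and 6 months within DBA/2J. At 12 months the lists of ribosomal protein, proliferation, MGnD, oxidative phosphorylation, rod, MHC, border-associated macrophage and complement genes rose and those of homeostatic and immediate early genes fell, by camera with the preset correlation. None of these calls held by fry or with an estimated correlation (smallest adjusted p = 0.282 with an estimated correlation). Apoe had 10970 ± 7956 CPM at 12 months against 1500 ± 646 at 6 months (n = 5 each), a log2 fold change of 2.87 ± 0.59, and was higher in 5 of 5 older animals than in any younger one. H2-D1 had 1707 ± 493 CPM against 843 ± 109 (n = 5 each). The share of mitochondrial counts was 2.07 ± 0.65% at 12 months and 1.15 ± 0.34% at 6 months, and of 15 mitochondrial genes tested, a set chosen after its values were seen, 13 were higher at an unadjusted p under 0.05 (median 1.14, smallest edgeR adjusted p 0.382).

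By edgeR, 0 of 12977 genes had an adjusted p under 0.05, with a smallest value of 0.253, and 474 had an unadjusted p under 0.05 (273 higher, 201 lower) where evenly spread p would give 649 and other splits had a median of 126. Of 12 alternatives, 8 gave 0, DESeq2 gave 60, sample quality weights 12, a random animal effect 5 and no filter on low counts 2. In simulated counts DESeq2 made 50 false calls and edgeR 0, and edgeR recovered 39.4% of genes changed 8-fold.

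Ribosomal protein genes had 23 of 36 members higher and 0 lower at an unadjusted p under 0.05, 9 adjusted over the list alone (median 0.64, 9.06e-14 by camera and adjusted p = 0.284 with an estimated correlation), such as Rpl3 (0.62 ± 0.16) and Rplp0 (0.68 ± 0.21). Oxidative phosphorylation genes had 7 of 36 higher and 0 lower, 0 adjusted over the list alone (median 0.63, 5.24e-06 by camera and adjusted p = 0.282 with an estimated correlation), such as Atp5b (0.66 ± 0.19) and Ndufa4 (1.25 ± 0.37). In the MGnD list 9 of 36 were higher and 1 lower, 4 higher adjusted over the list alone (median 0.58, 7.65e-06 by camera and adjusted p = 0.282 with an estimated correlation). Log2 fold changes were 2.42 ± 0.54 for Lyz2, 1.51 ± 0.36 for Cd63 and 0.83 ± 0.24 for Ctsl. They were 1.48 ± 1.38 for Spp1, for which 6-month animal 4 stood apart, 3.88 ± 2.25 for Lgals3, which had 0 counts in 4 of 5 younger animals, 0.68 ± 0.50 for Axl, 0.42 ± 0.18 for Trem2, -0.23 ± 0.50 for Clec7a and 0.60 ± 1.43 for Itgax.

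MHC genes had 6 of 17 members higher and 0 lower at an unadjusted p under 0.05, 3 adjusted over the list alone (median 0.67, 0.000159 by camera and adjusted p = 0.282 with an estimated correlation), with 1.02 ± 0.20 for H2-D1, 1.06 ± 0.22 for H2-K1 and 0.80 ± 0.18 for B2m. Complement genes had 4 of 13 higher and 0 lower, 3 adjusted over the list alone (median 0.08, 0.031 by camera and adjusted p = 0.367 with an estimated correlation), with 0.53 ± 0.13 for C1qa and 0.68 ± 0.16 for C1qb, and C4b had 130 ± 59.5 CPM against 5.66 ± 6.83 (n = 5 each). The complement call was lost without the retinas under 10000 genes (0.0585) and without 12-month DBA/2J animal 2, 3 or 5 or 6-month DBA/2J animal 2, 3 or 5 (0.0525 to 0.0909).

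Homeostatic genes had 6 of 33 members lower and 1 higher at an unadjusted p under 0.05 (median -0.25, 0.00312 by camera and adjusted p = 0.284 with an estimated correlation), a call lost without 12-month DBA/2J animal 5 (0.078). Log2 fold changes were -0.61 ± 0.18 for the TGF-beta receptor Tgfbr1, -1.25 ± 0.39 for Rhob, -0.76 ± 0.28 for P2ry13, -0.45 ± 0.19 for P2ry12 and 0.64 ± 0.16 for Olfml3. Tmem119 was at 0.19 ± 0.18, Cx3cr1 at -0.36 ± 0.19, Csf1r at -0.41 ± 0.24, Sall1 at -0.41 ± 0.28 and Fcrls at 0.34 ± 1.20. Immediate early and heat shock genes had 5 of 23 lower and 0 higher (median -0.46, 0.0254 by camera and adjusted p = 0.585 with an estimated correlation), with -1.39 ± 0.49 for Ier2 and -0.81 ± 0.33 for Btg2, a call lost without low-depth retinas (0.0727) and without 12-month DBA/2J animal 2, 3 or 5 or 6-month DBA/2J animal 1 or 2 (0.0506 to 0.335).

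Proliferation genes had 4 of 22 members higher and 0 lower at an unadjusted p under 0.05, 0 adjusted over the list alone (median 1.78, 1.17e-07 by camera and adjusted p = 0.282 with an estimated correlation). The mitotic kinase gene Aurkb had 21.5 ± 29.6 CPM against 0.0407 ± 0.091 and Birc5 16.6 ± 15.1 against 0.58 ± 0.904 (n = 5 each). Counts at 12 months summed 2 retinas per animal and those at 6 months came from 1. With the larger retina of each animal alone the median was 1.03 (jackknife SE 1.22). Rod markers had 15 of 17 positive changes and 1 past an unadjusted p of 0.05, Gngt1 at 2.06 ± 0.93 (median 1.18, 4.88e-06 by camera and adjusted p = 0.349 with an estimated correlation), and their summed CPM was 1890 ± 1010 against 831 ± 901 (n = 5 each). Of the younger animals, animal 1 had 2420 CPM, and the mean of the other 4 was 435 ± 189. Border-associated macrophage markers had 9 of 9 positive and 0 past an unadjusted p of 0.05 (median 0.92, 0.00237 by camera and adjusted p = 0.32 with an estimated correlation), with Ms4a7 at 2.94 ± 1.73 and Gas6, which the homeostatic list also holds, at 0.92 ± 0.58.

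The third comparison set 6-month DBA/2J against 12-month Gpnmb+, where age and genotype differ together. Immediate early and heat shock, proliferation, ribosomal protein and rod genes fell in the 6-month animals by camera with the preset correlation. None of these calls held by fry or with an estimated correlation (smallest adjusted p = 0.571 with an estimated correlation). Of the immediate early list 6 of 23 were lower at an unadjusted p under 0.05 (median -0.94, camera adjusted p 6.84e-08), with Ier3 at -1.74 ± 0.48. Of the proliferation list 5 of 22 were lower (median -1.97, 2.29e-06), with Mcm3 at -1.48 ± 0.59. Most Gpnmb+ animals gave 2 retinas and each 6-month animal 1. Mcm3 changed sign with a random animal effect, in a fit where the median log2 fold change of all genes was 1.09. For ribosomal proteins 1 of 36 was lower (median -0.26, 2.57e-05), Rpl5 at -0.81 ± 0.26. Of the rod markers 3 of 17 were lower (median -1.72, 4.98e-06), with the transducin subunit gene Gngt1 at -2.28 ± 0.94. Apoe had 1500 ± 646 CPM against 1971 ± 1765 (n = 5 each), a log2 fold change of -0.39 ± 0.55, and the other 12 genes fixed in advance lay between -2.19 ± 2.09 for Lgals3 and 1.66 ± 1.46 for Itgax. The share of mitochondrial counts was 1.15 ± 0.34% at 6 months and 2.23 ± 1.10% in Gpnmb+, and 12 of the 15 mitochondrial genes were lower at an unadjusted p under 0.05 (median -1.01, smallest edgeR adjusted p 0.782).

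By edgeR, 0 of 12977 genes had an adjusted p under 0.05, with a smallest value of 0.198, and 489 had an unadjusted p under 0.05 where evenly spread p would give 649 and other splits had a median of 368. DESeq2 gave 57 and the random animal effect 40, with 0 in the other 10 alternatives, and in simulated counts DESeq2 made 86 false calls and edgeR 7. Without the 5 Gpnmb+ retinas under 10000 genes, the camera adjusted p were 0.84 for immediate early genes, 0.84 for rods, 0.0634 for ribosomal proteins and 1.36e-09 for proliferation. The rod call was also lost without Gpnmb+ animal 2 (0.292) and the ribosomal call without Gpnmb+ animal 1 (0.0875).

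**Figure D3:**
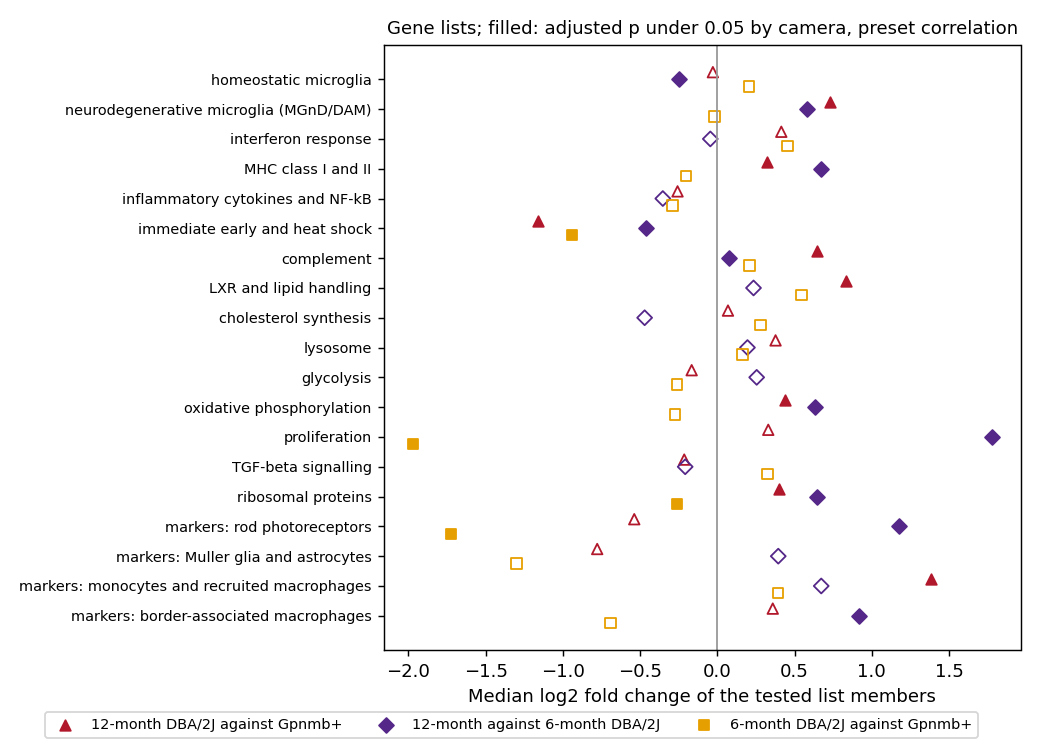
Median log2 fold change of the tested members (x axis) of gene lists (y axis) in the 3 comparisons of groups, 1 symbol per comparison. Filled symbols had an adjusted p under 0.05 by camera with the preset correlation: 8 lists for 12-month DBA/2J against Gpnmb+, 10 for 12-month against 6-month DBA/2J and 4 for 6-month DBA/2J against Gpnmb+.

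The last comparisons took the grade of each 12-month DBA/2J retina. In moderate retinas (n = 3 animals), 7 lists rose and 2 fell against Gpnmb+ (n = 5) by camera, 4 passed by fry, and 0 held with an estimated correlation (smallest adjusted p = 0.254 with an estimated correlation). Apoe had 19670 ± 15780 CPM against 1937 ± 1764, a log2 fold change of 3.34 ± 0.58, with an edgeR adjusted p of 0.165. Camera adjusted p were 1.17e-05 for MGnD genes (7 of 39 higher and 0 lower at an unadjusted p under 0.05, Lyz2 at 2.59 ± 0.61), 7.33e-09 for ribosomal proteins (24 of 36 higher, Rpl8 at 1.26 ± 0.32) and 2.96e-06 for oxidative phosphorylation (6 of 36 higher, Cox4i1 at 1.24 ± 0.35). They were 0.000193 for lipid handling, 0.00182 for complement (C1qa at 0.71 ± 0.18), 0.00119 for border-associated macrophage markers (Ms4a7 at 4.64 ± 1.82) and 0.00174 for rod markers, the last lost without 12-month DBA/2J animal 1 or Gpnmb+ animal 5 (0.0727 to 0.0998). The lists that fell were immediate early genes (17 of 23 lower, median -1.75, 2.27e-12, Jun at -1.83 ± 0.39) and homeostatic genes (6 of 34 lower and 1 higher, median -0.41, 2.60e-05), with P2ry12 at -0.94 ± 0.27, Tgfbr1 at -0.78 ± 0.26 and Sall1 at -1.24 ± 0.42.

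In mild retinas (n = 2 animals), immediate early genes (6 of 23 lower, median -0.83, camera adjusted p 0.00186, Ier2 at -2.66 ± 0.70) and rod markers (4 of 17 lower, median -1.72, 0.0255, Rbp3 at -8.09 ± 2.43) fell against Gpnmb+. These calls had adjusted p = 0.868 and 0.868 with an estimated correlation. They were lost with 1 retina per animal (0.0619 and 0.208) and without the retinas under 10000 genes (0.722 and 0.925, the rod list then changing sign). The first was also lost without 12-month DBA/2J animal 4 or Gpnmb+ animal 1 or 2 (0.0611 to 0.099) and the second without 12-month DBA/2J animal 5 or Gpnmb+ animal 2 (0.276 to 0.709). In severe retinas (n = 2 animals), immediate early genes fell (6 of 23 lower, median -0.93, 3.19e-05, Ier5 at -1.62 ± 0.60) and lipid handling genes rose (5 of 23 higher and 1 lower, median 0.63, 0.0135, Apoe at 2.69 ± 0.62). Their adjusted p = 0.953 and 0.953 with an estimated correlation, and the camera values were 0.353 and 0.0824 without the retinas under 10000 genes and 0.186 and 0.0969 without DBA/2J animal 3. Apoe was at 0.91 ± 0.63 and Tmem119 at 0.62 ± 0.28 in mild retinas, and Tmem119 at 0.95 ± 0.28 in severe ones. Between the stages, a linear trend was tested, with severe against mild as an alternative. Moderate retinas were not tested against the other grades, and a linear trend cannot show a difference particular to them.

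Along the trend from mild over moderate to severe, the log2 change per stage was 0.89 ± 0.61 for Apoe and 0.18 ± 0.28 for P2ry12. The trend rests on 7 sums of 5 animals, and with each retina on its own and the animal as a replicate block the changes were -0.09 for Apoe and -0.10 for P2ry12. Over the 13 genes fixed in advance it lay between -0.26 and 1.10, with unadjusted p of 0.173 to 0.864, and 0 of 26 lists passed by camera. The labels give no sex. Xist, an RNA that silences an X chromosome in female cells, was at 0 to 0.161 CPM in the mild retinas, 0 to 1240 CPM in the moderate and 1150 to 1670 CPM in the severe ones. A sum of Y-linked genes was at 113 to 286 CPM, 0 to 146 CPM and 0 to 0.398 CPM in the same order. These genes were chosen after their values were seen.

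By edgeR, 0 genes passed the adjusted threshold in the trend and in each stage. At an unadjusted p under 0.05 there were 248 genes for the trend, 865 for mild, 1350 for moderate and 683 for severe retinas, where evenly spread p would give 670 for the trend and 798 for each stage. Other splits of the animals had a median of 1137 such genes for moderate retinas and up to 2120, and were not made for the trend or the other 2 stages. In the same order, DESeq2 gave 22, 596, 296, 280 genes, the random animal effect 3, 3, 13, 32, and no filter on low counts 6, 31, 33, 10. Sample quality weights gave 7 in severe retinas and 0 in the other 3. In simulated counts DESeq2 made 104 false calls for the trend and 147 for moderate retinas, and edgeR recovered 6.06% and 21.2% of genes changed 8-fold.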

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

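Animals were compared within each group for the named genes and library measures, by whether the most extreme one stood apart from the rest by Dixon's criterion. It marked 5 of 105 groups of values, where chance gives about 5.2. The percent of counts in the top 50 genes was 63.2 in the left eye of Gpnmb+ animal 1, with 50.8 as the next value of 9 retinas. Spp1 was at 143 CPM in 6-month animal 4, with 22.6 next, and Lgals3 at 3.78 CPM in 6-month animal 5, where the other 4 animals were at 0. Olfml3 was at 2250 CPM in 12-month DBA/2J animal 5, with 3670 next, and Fcgr1 at 367 CPM in the same animal, with 527 next.

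Of the tests that follow, the one on macrophage markers, the counts of genes over other splits and the exact permutation tests of summed CPM were chosen after the results were seen. The lists looked at here were picked among 27, which the shares of splits do not take into account. Immediate early and heat shock genes were lower in 12-month DBA/2J than in Gpnmb+, with a median log2 fold change of -1.16. Thinning every animal to the smallest total left a median of -1.17 (jackknife SE 0.394). Thinning draws reads at random and keeps the expected proportions of an animal, so little change was to be foreseen. It therefore cannot decide whether depth, or what goes with low depth, is the cause. Without the 5 Gpnmb+ retinas under 10000 genes the median was -0.75 (SE 0.448), too imprecise to tell whether low complexity carries over 50% of it. A mean as far from 0 came from 2 of 100 splits of the animals, the real one included (real -1.3, highest other 1.36 in size), which excludes chance at the 5% level for this mean taken alone. Adjusted over the lists, camera with the preset correlation (6.04e-14) and fry (0.0497) passed 5%, and summed CPM (exact permutation p 0.00794, adjusted 0.0613) and camera (adjusted p = 0.289 with an estimated correlation) did not, so for a list picked among 27 chance stays open. Genotype, disease and handling of the tissue before the sort, in which such genes may respond, stay open and were not tested.

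MGnD genes were higher in 12-month DBA/2J than in Gpnmb+, with a median log2 fold change of 0.728 and Apoe at 2.48. Without the retinas under 10000 genes the median was 0.577 (jackknife SE 0.34), so a part played by low complexity cannot be told apart from a group difference. Other macrophages among the sorted cells are a candidate source of Apoe RNA, although the gates for FCRLS and against Ly6c are meant to select microglia and leave out monocytes. Fcrls RNA was low in these cells, at 37.97 ± 35.47 CPM in 12-month DBA/2J and 21.45 ± 24.59 in Gpnmb+ (n = 5 each). How far border-associated macrophages pass the gates was not tested. On this source, the median over 13 markers of monocytes and border-associated macrophages was 0.439, below Apoe by 2.04 (SE 0.697). These 13 leave out genes of the microglia lists, among them Lyz2, which was at 1.785 ± 0.52. The markers had an SD of 2.15, which leaves this source open. A mean as far from 0 came from 3 of 100 splits (real 0.81, highest other 1.14), which excludes chance at the 5% level for this mean taken alone. Adjusted over the lists, camera with the preset correlation (0.00657) and fry (0.0309) passed 5%, and summed CPM (exact permutation p 0.0159, adjusted 0.0613) and camera (adjusted p = 0.554 with an estimated correlation) did not, so for a list picked among 27 chance stays open. Genotype and disease are the design's own explanations and cannot be separated here.

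Proliferation genes were higher at 12 than at 6 months in DBA/2J, with a median log2 fold change of 1.78. Older animals gave 2 retinas and younger ones 1, so rare dividing cells may be caught more often in the older group. With the larger retina of each animal alone the median was 1.03 (jackknife SE 1.22), and the number of retinas cannot be told apart from age on this value, since the SE is as large. A mean as far from 0 came from 3 of 100 splits (real 2.43, highest other 2.91), which excludes chance at the 5% level for this mean taken alone. Adjusted over the lists, camera with the preset correlation (1.17e-07) passed 5%, and summed CPM (exact permutation p 0.0556, adjusted 0.125), fry (0.2) and camera (adjusted p = 0.282 with an estimated correlation) did not, so for a list picked among 27 chance stays open. Age and the course of disease, which the labels call early at 6 months, differ together here. The summed CPM was 487 ± 218 in 12-month Gpnmb+, 435 ± 211 in 12-month DBA/2J and 222 ± 42.3 at 6 months (n = 5 each). The lowest Gpnmb+ animal (305 CPM) lay above the highest 6-month animal (269 CPM). For these sums this argues against disease in DBA/2J as the main source, since the control strain at 12 months was not lower. Age and a smaller part played by disease stay open and were not tested.

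Counts of calls were compared with those of other splits of the same animals. With 0 genes called by edgeR (unadjusted p under 0.05: 676, 474, 489 and 1350; DESeq2: 108, 60, 57 and 296), 100 of 100 splits in each of the 3 comparisons of groups and 56 of 56 for moderate retinas give as many by construction, so this count decides nothing. The highest other counts were 1, 0, 1 and 22. For moderate retinas 9 other splits called any gene. Whether the split with 22 genes against a real 0 reflects some structure among those animals was not tested. As many genes at an unadjusted p under 0.05 came from 8 of 100 splits for 12-month DBA/2J against Gpnmb+ (highest other 832), 11 of 100 for 6-month DBA/2J against Gpnmb+ (647) and 11 of 56 for moderate retinas (2120), so chance cannot be excluded there. For 12 against 6 months it was 1 of 100 (highest other 394), which excludes chance at the 5% level only as measured by these splits, whose other counts had a median of 126. The real 474 lies below the 649 that evenly spread p would give. For lists called by camera with the preset correlation, 2 of 100 splits gave as many as the 8 of 12-month DBA/2J against Gpnmb+ (highest other 8). As many as the 10 of 12 against 6 months came from 1 of 100 (highest other 9). These shares exclude chance at the 5% level only for these counts, unadjusted for the several counts compared. Splits of 12 against 6 months also mix animals with 2 retinas and animals with 1. With an estimated correlation 0 lists were called in either comparison, so chance stays open for the lists themselves. For 6-month DBA/2J against Gpnmb+, 23 of 100 splits gave 4 or more (highest other 6), and for moderate retinas 3 of 56 gave 9 or more (highest other 10), so there chance cannot be excluded.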

How the results depend on the processing

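The alternatives with 1 retina per animal, with quality weights and without retinas under 10000 genes were chosen after seeing the data, as were RLE scaling and leaving out low-depth retinas or 1 animal for the lists. Of 565 values of called lists under alternatives, 420 kept direction and call, 144 lost the call and 1 reversed. Of 4710 values of single named genes, none of them called by edgeR, 4501 kept direction and side of the threshold, 81 passed it and 128 changed sign or went to 0. The cause of these changes was not tested. An alternative based on another source of counts was not run, since the table of the whole series holds FPKM. By depth alone, a count of 0 in a retina allows up to 3.07 CPM. At the real depths, spread and number of animals, edgeR recovered few of the genes changed 2-fold in simulated counts (mean log2 CPM of at least 4). It recovered 1.49% for 12-month DBA/2J against Gpnmb+ and 0% for moderate retinas. Which of depth, spread and number of animals sets this limit was not tested. Genes that the stricter filter removed, or that a fit could not test, have no value there. With a random animal effect the median log2 fold change of all genes was 0.59, -0.428, 1.09 in the 3 comparisons of groups, against 0.0543, 0.0099, 0.0254 in the fit by animal. Signs of single genes in those fits therefore include a shift of the median gene.

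For 12-month DBA/2J against Gpnmb+, edgeR called 0 genes (676 at an unadjusted p under 0.05), against 108 with DESeq2 and 8 with a random animal effect. Leaving out 1 animal gave 0 to 1 genes: Olfml3 without 12-month animal 5. Camera called 8 lists, against 0 with an estimated correlation and 1 with 1 retina per animal (immediate early and heat shock) and 2 to 8 when 1 animal was left out. Lists gaining a call under an alternative were homeostatic microglia (lower at 0.0286 with RLE scaling, 0.0373 without the retinas under 10000 genes, 0.0488 without 12-month DBA/2J animal 3, 0.0329 without Gpnmb+ animal 1), inflammatory cytokines and NF-kB (lower at 0.0297 with the animal number as a block, 0.0315 without 12-month DBA/2J animal 2), rod photoreceptors (higher at 0.00194 without the retinas under 10000 genes, 0.0174 without Gpnmb+ animal 2). Log2 fold changes that changed sign were those of Cx3cr1 (-0.029), Csf1r (0.040), Sall1 (-0.43), Ccr2 (1.15). With no filter Cx3cr1 was at 0.00094, and by retina Cx3cr1 was at 0.053. With a random animal effect Cx3cr1 was at 0.0018, and with 1 retina per animal Cx3cr1 was at 0.013. With DESeq2 Csf1r was at -0.019, and with RLE scaling Csf1r was at -0.019. Without retinas under 10000 genes Csf1r was at -0.36 and Sall1 at 0.044, and with quality weights Csf1r was at -0.12. With 1 animal left out the ranges were -0.12 to 0.11 for Cx3cr1, -0.16 to 0.16 for Csf1r, -0.069 to 1.57 for Ccr2.

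For 12-month against 6-month DBA/2J, edgeR called 0 genes (474 at an unadjusted p under 0.05), against 60 with DESeq2, 2 with no filter (Apoe, Ccl12), 5 with a random animal effect (Cxcl13, C1qa, Kcnk12, Senp8, Gm37985) and 12 with quality weights. Camera called 10 lists, against 0 with an estimated correlation and 0 by fry. Gained under an alternative were calls of TGF-beta signalling (lower at 0.0353 without 12-month DBA/2J animal 1), LXR and lipid handling (higher at 0.0344 without 12-month DBA/2J animal 4). A change of sign was seen in the log2 fold changes of Clec7a (-0.23), Itgax (0.60), Fcrls (0.34), F13a1 (1.82). With 1 retina per animal Clec7a was at 0.20, and with a random animal effect Itgax was at -0.18 and Fcrls at -1.46. With quality weights Fcrls was at -0.42. Ranges over left-out animals were -0.66 to 0.024 for Clec7a, -0.15 to 0.72 for Fcrls, -0.053 to 5.63 for F13a1.

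For 6-month DBA/2J against Gpnmb+, edgeR called 0 genes (489 at an unadjusted p under 0.05), against 57 with DESeq2 and 40 with a random animal effect. Camera called 4 lists, against 0 with an estimated correlation, 0 by fry and 1 without retinas under 10000 genes (proliferation). Under alternatives camera also called border-associated macrophages (lower at 0.0395 without Gpnmb+ animal 1, 0.013 without 6-month DBA/2J animal 1), oxidative phosphorylation (lower at 0.028 without Gpnmb+ animal 2), interferon response (higher at 0.034 without 6-month DBA/2J animal 3). Log2 fold changes that changed sign were those of Apoe (-0.39), Spp1 (0.11), Trem2 (-0.043), P2ry12 (0.23), Sall1 (-0.018), Mcm3 (-1.48), Gngt1 (-2.28), Pde6g (-2.78), Sag (-1.56). Without retinas under 10000 genes Spp1 was at -0.68, Trem2 at 0.12, P2ry12 at -0.0040, Sall1 at 0.45, Gngt1 at 0.17, Pde6g at 0.64 and Sag at 0.18, and with quality weights Spp1 was at -1.44 and Sall1 at 0.32. By retina Trem2 was at 0.015 and Sall1 at 0.20, and with 1 retina per animal Trem2 was at 0.079 and Sall1 at 0.067. With no filter Sall1 was at 0.0076, and with a random animal effect Sall1 was at 0.38 and Mcm3 at 0.016. With 1 animal left out the ranges were -0.64 to 0.28 for Apoe, -1.35 to 1.32 for Spp1, -0.097 to 0.022 for Trem2, -0.17 to 0.30 for Sall1.

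For the stage trend, edgeR called 0 genes (248 at an unadjusted p under 0.05), against 22 with DESeq2, 6 with no filter, 3 with a random animal effect (Ddx3y, Eif2s3y, Gm20633) and 1 for severe against mild (Xist). Camera called 0 lists, against 2 with 1 retina per animal (oxidative phosphorylation and ribosomal proteins) and 0 to 2 when 1 animal was left out. Further lists called under an alternative were oxidative phosphorylation (lower at 0.00627 with 1 retina per animal, 0.000933 without 12-month DBA/2J animal 5), ribosomal proteins (lower at 0.00813 with 1 retina per animal, 0.000769 without 12-month DBA/2J animal 5), interferon response (higher at 0.00403 without 12-month DBA/2J animal 1), proliferation (higher at 0.000419 without 12-month DBA/2J animal 1). A change of sign was seen in the log2 fold changes of Spp1 (-0.15), Lgals3 (0.65), Itgax (0.62), Trem2 (-0.11), Tmem119 (0.16), Cx3cr1 (0.057), Csf1r (-0.042), Sall1 (-0.10). By retina Spp1 was at 0.019, and with quality weights Spp1 was at 0.080, Csf1r at 0.18 and Sall1 at 0.12. With 1 retina per animal Spp1 was at 0.21, Lgals3 at -6.56, Itgax at -0.60, Tmem119 at -0.012, Csf1r at 0.42 and Sall1 at 0.29, and with a random animal effect Csf1r was at 0.0027. Ranges over left-out animals were -0.89 to 0.47 for Spp1, -0.84 to 2.12 for Lgals3, -0.95 to 2.16 for Itgax, -0.27 to 0.084 for Trem2, -0.092 to 0.53 for Cx3cr1, -0.27 to 0.28 for Csf1r, -0.32 to 0.28 for Sall1.

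For mild retinas against Gpnmb+, edgeR called 0 genes (865 at an unadjusted p under 0.05), against 596 with DESeq2, 31 with no filter and 3 with a random animal effect (Ampd3, Cst3, CT010467.1). Leaving out 1 animal gave 0 to 2 genes: Tmc6, Emc8 without 12-month animal 4. Camera called 2 lists, against 0 with an estimated correlation, 1 by fry (a list not called by camera, cone photoreceptors, 2 tested, adjusted p 0.0158, and adjusted p = 0.775 with an estimated correlation), 1 without retinas under 10000 genes (proliferation) and 0 with 1 retina per animal and 0 to 3 when 1 animal was left out. Calls gained under an alternative were those of proliferation (lower at 0.0175 without the retinas under 10000 genes, 0.00978 without 12-month DBA/2J animal 4, 0.0309 without Gpnmb+ animal 4), ribosomal proteins (lower at 0.00594 without 12-month DBA/2J animal 4, higher at 0.00201 without 12-month DBA/2J animal 5), oxidative phosphorylation (higher at 0.0124 without 12-month DBA/2J animal 5). The rod list changed sign without retinas under 10000 genes (adjusted p 0.925). Log2 fold changes that changed sign were those of Spp1 (1.10), Lgals3 (-0.80), Itgax (-0.40), P2ry12 (-0.083), Cx3cr1 (0.18), Csf1r (0.32), Sall1 (0.13). With 1 retina per animal Spp1 was at -0.38, Cx3cr1 at -0.72, Csf1r at -0.42 and Sall1 at -0.40, and with a random animal effect Itgax was at 0.061. Without retinas under 10000 genes Itgax was at 0.31, Cx3cr1 at -0.095 and Csf1r at -0.10, and without low-depth retinas P2ry12 was at 0.041. With quality weights Cx3cr1 was at -0.0012. With 1 animal left out the ranges were -0.52 to 2.32 for Spp1, -8.71 to 0.17 for Lgals3, -3.04 to 0.45 for Itgax, -0.46 to 0.16 for P2ry12, -0.74 to 0.70 for Cx3cr1, -0.30 to 0.70 for Csf1r, -0.52 to 0.51 for Sall1.

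For moderate retinas against Gpnmb+, edgeR called 0 genes (1350 at an unadjusted p under 0.05), against 296 with DESeq2, 33 with no filter, 1 by retina (Apoe) and 13 with a random animal effect. Leaving out 1 animal gave 0 to 4 genes: Gpr34 without 12-month animal 2 and Apoe, C1qb, Ctss, B2m without 12-month animal 5 and Apoe, Ttc33 without Gpnmb+ animal 5. Camera called 9 lists, against 0 with an estimated correlation and 4 by fry, all among the 9. Called under an alternative alone were MHC class I and II (higher at 0.0335 without the retinas under 10000 genes, 0.0471 without 12-month DBA/2J animal 1, 0.00383 without Gpnmb+ animal 2), glycolysis (higher at 0.00444 without the retinas under 10000 genes, 0.0105 without Gpnmb+ animal 2), proliferation (higher at 0.03 without 12-month DBA/2J animal 2), TGF-beta signalling (lower at 0.0132 without 12-month DBA/2J animal 2). A change of sign was seen in the log2 fold changes of Clec7a (-0.58), Trem2 (0.29), Tmem119 (0.13), Gngt1 (1.21), Rom1 (1.36). With 1 retina per animal Clec7a was at 0.20, and with a random animal effect Trem2 was at -0.045 and Tmem119 at -0.0016. Without retinas under 10000 genes Tmem119 was at -0.16. Ranges over left-out animals were -2.24 to 0.0076 for Clec7a, -0.30 to 0.37 for Tmem119, -0.011 to 2.45 for Gngt1, -0.34 to 3.84 for Rom1. Nr1h3, at 9.42, went to 0 with 1 animal left out (0 to 10.11).

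For severe retinas against Gpnmb+, edgeR called 0 genes (683 at an unadjusted p under 0.05), against 280 with DESeq2, 10 with no filter, 32 with a random animal effect and 7 with quality weights. Camera called 2 lists, against 0 with an estimated correlation, 0 by fry and 0 without retinas under 10000 genes and 1 to 6 when 1 animal was left out. Other lists that an alternative called were MHC class I and II (higher at 0.0432 with 1 retina per animal, 0.00214 without 12-month DBA/2J animal 1, 0.00357 without Gpnmb+ animal 2), proliferation (lower at 0.000527 without 12-month DBA/2J animal 3), rod photoreceptors (lower at 0.0301 without Gpnmb+ animal 1, 0.0211 without Gpnmb+ animal 5), lysosome (higher at 0.0172 without Gpnmb+ animal 2, 0.0365 without Gpnmb+ animal 5), neurodegenerative microglia (MGnD/DAM) (higher at 0.0211 without Gpnmb+ animal 5), complement (higher at 0.0469 without Gpnmb+ animal 5). Log2 fold changes that changed sign were those of Spp1 (0.82), Lgals3 (0.54), Itgax (0.87), Csf1r (0.24), Sall1 (-0.064). Without retinas under 10000 genes Lgals3 was at -0.18, Csf1r at -0.19 and Sall1 at 0.35, and with quality weights Lgals3 was at -2.56, Itgax at -2.98 and Sall1 at 0.22. With 1 retina per animal Lgals3 was at -5.49, and by retina Sall1 was at 0.038. With a random animal effect Sall1 was at 0.20. With 1 animal left out the ranges were -0.98 to 2.03 for Spp1, -8.62 to 1.53 for Lgals3, -8.56 to 1.88 for Itgax, -0.11 to 0.50 for Csf1r, -0.31 to 0.22 for Sall1. Apoc2, at 7.49, went to 0 with 1 animal left out (0 to 8.58).

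The animal numbers of the labels are shared between groups, so each comparison was also fitted with the number as a replicate block, and the stage trend by retina with the animal as a replicate block. The block in the stage comparisons against Gpnmb+ was chosen after seeing the data. Deviations from the group mean of same-numbered animals correlated at -0.0332 to 0.0486, -0.00927 to 0.0337, -0.0485 to 0.103 in the 3 pairs of groups, and 3, 1, 1 of 5 animals correlated best with their own number, so the numbers do not pair animals. With the block edgeR called 4 genes for moderate retinas against Gpnmb+, 1 for severe retinas against Gpnmb+ and 0 for the other 5. In the same fits camera called 7 lists for 12-month DBA/2J against Gpnmb+, 10 for 12-month against 6-month DBA/2J, 4 for 6-month DBA/2J against Gpnmb+, 9 for moderate retinas against Gpnmb+, 1 for severe retinas against Gpnmb+ and 0 for the other 2. Lists called without the block and not with it were MHC class I and II (0.103) and ribosomal proteins (0.11) for 12-month DBA/2J against Gpnmb+, immediate early and heat shock (0.298) and rod photoreceptors (0.227) for mild retinas against Gpnmb+, LXR and lipid handling (0.0624) for severe retinas against Gpnmb+. The genes were Btg2, Egr1, Jun, AY036118 in moderate and AY036118 in severe retinas. In the block fit for 12-month against 6-month DBA/2J, Fcrls turned from 0.34 to -0.57. In the block fit for 6-month DBA/2J against Gpnmb+, Sall1 turned from -0.018 to 0.035. In the block fit for the stage trend, Apoe turned from 0.89 to -0.092, Lgals3 turned from 0.65 to -2.47, Itgax turned from 0.62 to -2.75, P2ry12 turned from 0.18 to -0.098, Fcrls turned from 1.10 to -0.56. In the block fit for mild retinas against Gpnmb+, Itgax turned from -0.40 to 1.83, Cx3cr1 turned from 0.18 to -0.020. In the block fit for severe retinas against Gpnmb+, Itgax turned from 0.87 to -0.52, Sall1 turned from -0.064 to 0.19.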

Other observations

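Some genes outside the fixed lists had small p and were chosen after their values were seen. Fcgr1, a high-affinity receptor for antibodies, had 517 ± 86 CPM in 12-month DBA/2J against 254 ± 51.3 in Gpnmb+ and 290 ± 45.4 at 6 months (n = 5 each), and it was higher in 5 of 5 12-month DBA/2J animals than in any animal of the other groups. Ccl12, a chemokine gene, had 968 ± 266 CPM at 12 months against 200 ± 104 at 6 months (n = 5 each), with 5 of 5 older animals above every younger one. Neither passed edgeR's adjustment over all genes (adjusted p 0.313 for Fcgr1 against Gpnmb+ and 0.253 for Ccl12 between the ages).

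The summed CPM of each of 27 lists per animal was compared by an exact two-sided permutation test over 252 splits. It used the log2 of the sum plus 1 and was chosen after the list results were seen. Its smallest p is 0.0079. For 12 against 6 months 8 lists passed after Benjamini-Hochberg adjustment (exact permutation adjusted p 0.0268 each). Older animals gave 2 retinas and younger ones 1, and genes detected per retina were 10703 to 15046 against 13818 to 16716. Age therefore cannot be told apart from these differences between the libraries for any of the 8 lists. The sums of MGnD genes were 33100 ± 9560 and 20000 ± 843 CPM, of MHC genes 7600 ± 1250 and 4570 ± 330, of complement 12700 ± 1200 and 9930 ± 868, and of lipid handling 12600 ± 8040 and 2890 ± 680 (n = 5 each). They were 3250 ± 420 and 2240 ± 133 for oxidative phosphorylation, 13200 ± 2640 and 8690 ± 619 for ribosomal proteins, 950 ± 432 and 221 ± 119 for monocyte markers, and 1810 ± 181 and 2460 ± 151 for TGF-beta signalling, which was lower at 12 months. For the same ages camera with the preset correlation did not call lipid handling (0.19), monocyte markers (0.0916) or TGF-beta signalling (0.0505), although it called the first without 12-month DBA/2J animal 4 (0.0344) and the last without 12-month DBA/2J animal 1 (0.0353). Fry and camera with an estimated correlation called none of the 8 (smallest adjusted p = 0.282 with an estimated correlation and 0.165 by fry). Sums are carried by their most abundant members. Apoe took 10970 CPM of the lipid sum at 12 months and 1500 CPM at 6, and Lyz2 857 and 160 CPM of the monocyte sum, so these calls rest mostly on single genes. The MGnD list holds Apoe and Lyz2 as well, and most of the rise of its sum is that of Apoe. Against Gpnmb+, 0 lists passed for 12-month DBA/2J (smallest exact permutation adjusted p 0.0613, 10 unadjusted under 0.05) and 0 for 6-month DBA/2J (smallest 0.214, 3 unadjusted). Gpnmb+ animal 5, picked after its values were seen, overlapped 12-month DBA/2J in several sums. It exceeded the lowest DBA/2J animal for MGnD (24400 against 23900 CPM), complement (11400, 11200), lipid handling (6330, 5130), ribosomal proteins (11600, 9840) and monocyte markers (555, 540). It lay below for MHC (5100, 5520) and oxidative phosphorylation (2530, 2680).

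X- and Y-linked RNA was looked at after alternatives for the stage trend called Xist, Ddx3y and Eif2s3y. Xist exceeded the sum of 4 Y-linked genes in 3 of 5 12-month DBA/2J, 3 of 5 6-month DBA/2J and 4 of 5 Gpnmb+ animals, and the eyes of an animal did not differ in which was higher. The mild retinas came from DBA/2J animals 4 and 5, in which the Y-linked sum was higher, and the severe retinas from animals 1 and 3, in which Xist was higher. The mild and severe grades therefore cannot be separated from this difference, and no test was made on it. The comparison of mild retinas with Gpnmb+ carries it as well, since Xist was higher in 4 of 5 Gpnmb+ animals. The right eye of Gpnmb+ animal 5 held both, with 125 CPM of Xist and 227 CPM of the Y-linked sum, where the left eye had 0 and 198 CPM.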
